A study of Homo sapiens with 6 samples.

How the data were processed

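RNA abundance was measured by sequencing in Hep3B, an established human hepatocellular carcinoma line. Per the labels, 3 samples were kept at 20% oxygen and 3 at 1% oxygen for 24 hours. Per the labels' protocols, RNA was extracted with TRIzol, treated with deoxyribonuclease and turned into libraries with a SMARTER mRNA-seq kit. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here, and neither is whether counting used strand. Nothing in the labels says that the samples were separate cultures, so p-values measure only the spread between these samples, which may be technical.

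The deposited table holds, for each entry, a read count and an FPKM value per sample, a false discovery rate and a log2 fold change. Counts were deposited by the authors as whole numbers without normalization, per the file headers and the values. FPKM values are the authors' own, per the file headers, and relate counts to transcript length and library total. The adjusted p-values (FDR) and the log2 fold changes are those of the authors' comparison, per the file headers, with positive values for entries higher at 1% oxygen. Sample columns carry the oxygen level and a number in their names and were matched to the sample titles by them.

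The table has 2681 entries with values, of which 2488 carry an Ensembl gene ID, 3 an Ensembl transcript ID and 190 a name of the form NewGene with a number. An external name table matched 2482 of the Ensembl gene IDs. The largest FDR in the authors' deposited table is 0.00999 and the smallest absolute log2 fold change is 1.00, so the table holds only entries past limits of 0.01 and 1. Genes that changed less are not analysed here. A gene without an entry can have been unchanged, little changed or not expressed. It can also have changed by more than 1 on the log2 scale with an FDR above 0.01. Every count of calls below rests on entries already selected on these same 6 samples and is not independent evidence of their change.

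Before the data were examined, the groups, the test (edgeR quasi-likelihood on counts with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05), 37 gene lists, the rule for named genes and a set of alternatives were fixed. One departure was needed. TMM assumes that most features do not change, and here each listed entry does: TMM over the listed entries moved the fold changes by a median of -0.53 on the log2 scale. Instead, each library's scale was recovered from the log2 fold changes in the authors' deposited table and the counts beside them, over 1442 entries with more than 200 counts in each library. The fit left a median absolute residual of 0.000201 on the log2 scale. Recovered scales were 1.06, 1.02 and 1.11 for normoxia replicates 1 to 3 and 0.994, 0.844 and 0.997 for hypoxia replicates 1 to 3. Normalized counts are counts divided by these scales. The scale is thus the authors' own, and the fold changes given here are not a check of it.

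The 6 leading entries by fold change were left out of all fits, because their log2 fold change in the authors' deposited table lay more than 1 from that of their own counts. The other 2675 entries deviated by a median of 0.000405 and at most 0.0516. filterByExpr removed 0 entries. The common dispersion was 0.0494. Adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the 2675 entries, and standard errors (SE) are the absolute log2 fold change over the square root of F. For an entry at 0 counts in all libraries of a group, the fold is a lower bound against a floor of 3 counts over the group. Where 1 to 3 counts make up a baseline, an exact Poisson interval (95%) of those counts is given with the ratio of mean normalized counts. Floors and intervals cover counting error only. Values of some single entries are not reported here.

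Named genes follow a rule fixed beforehand: sentinel genes of oxygen response and hepatocyte identity, the 10 largest rises and 10 largest falls among called entries with a gene symbol that is not a clone or LINC name, a mean of at least 5 CPM of listed counts and no overlap between groups, and up to 4 members of each list with the largest absolute change. Any other name is said to have been chosen after its values were seen. Lists with at least 5 entries (23 of 37) were tested with limma camera on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, two-sided and Benjamini-Hochberg adjusted. The camera test compares a list with the other listed entries, not with unchanged genes. None of the 23 lists passed camera with an estimated correlation (smallest adjusted p = 0.0697 with an estimated correlation), where 4 had an unadjusted p under 0.05.

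Coordinates, biotypes, neighbours and GC content come from GENCODE 29, whose coordinates are on GRCh38, and were joined by Ensembl gene ID. GC content is that of a gene's longest transcript and was found for 2485 of the 2675 entries. For the 138 named genes, the share of 31-mers of the longest transcript that transcripts of other genes hold on either strand was computed. It was over 80% for 5 genes, IRF9, MATR3, CD68, SRXN1 and NOP2, so that their counts are uncertain. For 14 others it lay between 30% and 80%: IDH3A, TIGAR, CCNE2, HSPD1, DDIT4, HSPA8, SLC2A3, CEBPA, UGT1A1, CP, AKR1B10, CA9, ADH1C and AQP1.

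Alternatives were RLE, upper quartile and TMM scaling, listed totals, totals from the ratio of counts to FPKM, DESeq2, limma voom, other low-count filters, glmTreat, an adjusted p under 0.01, a replicate block and leaving out each library. For the lists, an estimated correlation, fry and an exact direction test were also run. The recovered scale was chosen after seeing the data, which turned the planned TMM scaling into an alternative. Removal of GC trends, adjustment over all 58780 GENCODE 29 genes, FPKM-based scaling, the exact tests, the pathway tests and the fit with the 6 leading entries were also added after seeing the data. The edgeR step was tested on simulated counts for the 2675 entries: it recovered 71% of 100 genes changed by 1 on the log2 scale and 99% of 100 genes changed by 2, and called 12 of 2475 unchanged genes. In a simulated list test over 23 lists, camera called the 1 raised list and 0 others. Both simulations drew genes independently and left most of them unchanged. In the data each listed entry was selected as changed, and the estimated correlation within a list reached 0.481. The simulations therefore do not show how the tests behave on such entries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and scipy 1.17.1.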

Results

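The data are messenger RNA counts from Hep3B cells after 24 hours at 20% oxygen (normoxia, n = 3) or 1% oxygen (hypoxia, n = 3), and the comparison asks which transcripts differ between the oxygen levels. Over the listed entries, the normoxia libraries held 6128947, 5474597 and 5727663 counts and the hypoxia libraries 10134230, 9905692 and 9994572. These totals cover only entries that the authors selected as changed, so they are not library depths. GAPDH took the largest part of each, between 3.67% and 7.90%. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom between 13.1 and 268), so none was treated as a copy of another library. That comparison cannot tell separate cultures from separate preparations of 1 culture.

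Genes of the oxygen response rose at 1% oxygen. ANGPTL4, a secreted lipase inhibitor, went from 420 ± 45.2 to 40125 ± 13744 normalized counts (SD, n = 3 per group), 95.6-fold. CA9, a carbonic anhydrase of the cell surface, rose 59.0-fold, from 389 ± 94.2 to 22998 ± 6054 normalized counts, and NDRG1 rose 40.5-fold, from 9186 ± 1147 to 372034 ± 14953. The angiogenic factor VEGFA rose 12.5-fold and the glucose transporter SLC2A1 9.74-fold. The hepatocyte proteins ALB and AFP fell by 1.28 and 2.05 on the log2 scale.

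All 11 sentinel genes with an entry passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as did all 2675 entries. Adjusted p was 4.22e-06 for ANGPTL4 (log2 fold change 6.58, SE 0.30), 4.71e-06 for CA9 (5.88, SE 0.29), 2.01e-06 for NDRG1 (5.34, SE 0.18) and 7.44e-06 for VEGFA (3.64, SE 0.21). The mitophagy receptor BNIP3 rose by 2.13 on the log2 scale, the peptide hormone gene ADM by 3.02, the pyruvate dehydrogenase kinase PDK1 by 1.98 and the lactate dehydrogenase subunit LDHA by 1.98. The falls of ALB (adjusted p = 0.000508) and AFP (adjusted p = 0.000341) started from low levels, 370 ± 61.1 and 312 ± 88.9 normalized counts. Among the sentinels, EPO, EGLN3, HIF1A and EPAS1 had no entry among those analysed here. In GENCODE 29 on GRCh38, CA9 lies on chromosome 9 from 35673856 to 35681159 and shares 34.9% of its transcript sequence with ARHGEF39 on the opposite strand. ANGPTL4 lies on chromosome 19 from 8363289 to 8374373, VEGFA on chromosome 6 from 43770184 to 43786487 and NDRG1 on chromosome 8 from 133237171 to 133302022.

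**Figure D1:**
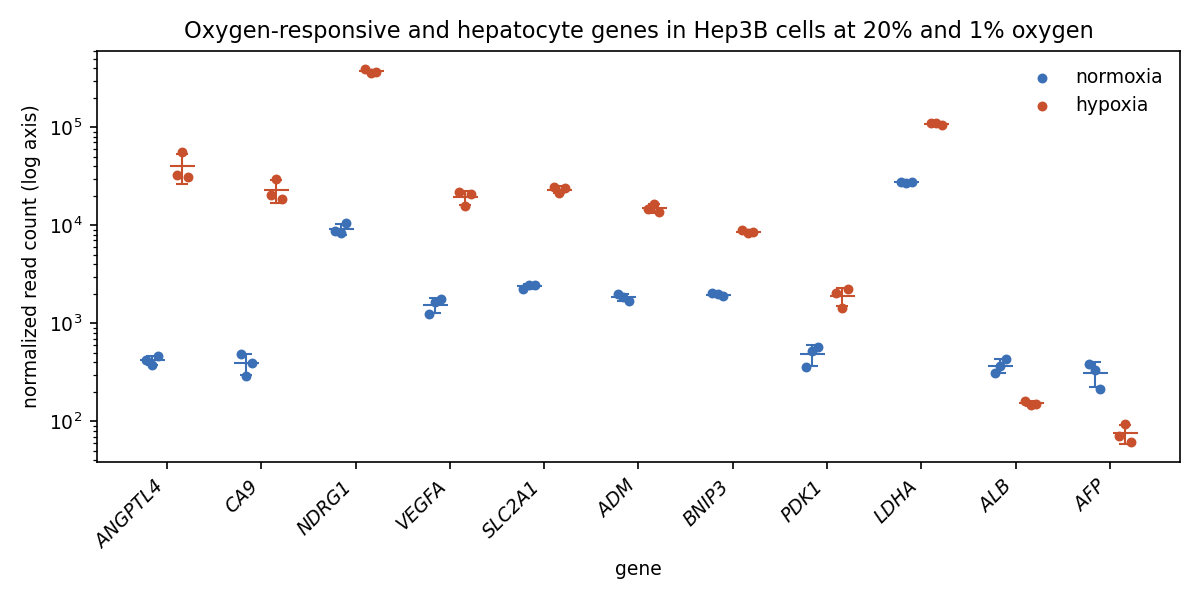
Normalized read counts (log axis) of the 11 sentinel genes with an entry, one point per library, with bars for the mean and SD of 3 libraries per group. The 3 hypoxia points lie above the 3 normoxia points in 9 genes, from ANGPTL4 to LDHA, and below them in ALB and AFP.

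Genes that carry glucose through glycolysis rose together. Of 24 list members 18 had an entry, and 18 were higher and 0 lower. Adjusted over the list alone, 18 passed. Every entry had been selected as changed, so that count adds no support, here or in the lists below. SLC2A3, a neuronal-type glucose transporter, rose 86.6-fold from 2.56 ± 3.01 to 229 ± 65.4 normalized counts, ENO2 20.6-fold, ALDOC 20.3-fold and the regulatory kinase gene PFKFB4 15.7-fold. The median of the list was a log2 fold change of 1.86 (camera adjusted p = 0.000614, and adjusted p = 0.272 with an estimated correlation). The fold of SLC2A3 is imprecise, since its baseline rests on few reads: without normoxia replicate 2, 2 normoxia counts remained and the ratio of mean normalized counts was 253 (95% exact Poisson interval of those counts, 70.1 to 2091). SLC2A3 shares 39.9% of its transcript sequence with other genes, mostly SLC2A14.

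Of 25 genes of the hypoxia response outside glycolysis, 22 had an entry, with 22 higher and 0 lower, and 22 adjusted over the list alone. NDUFA4L2, a mitochondrial protein gene, rose 90.5-fold and the adenylate kinase AK4 100.3-fold, from 3.09 ± 2.01 to 326 ± 51.5 normalized counts. The baseline of AK4 rests on few reads, and without normoxia replicate 3 its fold was 159. KISS1R, a G protein-coupled receptor, had 0 counts in each normoxia library and 425 ± 203 normalized counts in hypoxia, at least 425-fold higher. The list passed camera (median log2 fold change 2.98, also with KISS1R at its bound, adjusted p = 3.05e-06, and adjusted p = 0.191 with an estimated correlation). In the list of oxygen sensors and HIF subunits, 1 of 12 members had an entry, the transcriptional regulator CITED2, which rose 8.81-fold.

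Of 22 secreted factors 11 had an entry, 9 higher and 2 lower, and 11 passed adjusted over the list alone. The growth factor PDGFB rose 143-fold, from 57.5 ± 24.4 to 8272 ± 261 normalized counts, and the binding proteins IGFBP3 and IGFBP1 rose 41.5-fold and 23.1-fold. The chemokine CXCL8 and the cytokine GDF15 fell by 2.43 and 1.19 on the log2 scale, and CXCL8 fell by 3.32 without hypoxia replicate 3. The list had a median log2 fold change of 3.64 (camera adjusted p = 0.0311, and adjusted p = 0.218 with an estimated correlation), and its call ended when GC trends within the groups were removed (adjusted p = 0.0526, range over the camera alternatives 0.0196 to 0.425). The list stayed called when the GC trend of each library was removed. The direction of its entries did not pass an exact test against the other entries (two-sided, adjusted p = 0.211, and 0.335 within bins of GC content).

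Genes of collagen, its hydroxylation and its crosslinking rose, with 8 of 18 members listed, 8 higher and 0 lower, 8 adjusted over the list alone. The crosslinking oxidase LOX rose 27.5-fold, LOXL4 7.38-fold, LOXL2 6.01-fold and the prolyl hydroxylase subunit P4HA1 8.52-fold (camera adjusted p = 0.0197, and adjusted p = 0.370 with an estimated correlation). Adhesion and mesenchymal genes had 8 of 21 members listed, 8 higher and 0 lower, 8 adjusted over the list alone. Among them were the integrin ITGA5 (8.83-fold), the transcription factors ZEB2 (4.53-fold) and SNAI2 (3.47-fold) and the cytokine TGFB1 (3.63-fold). Camera gave adjusted p = 0.0311 for that list, and adjusted p = 0.218 with an estimated correlation.

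Autophagy and mitophagy genes had 5 of 16 members listed, 5 higher and 0 lower, 5 adjusted over the list alone, with BNIP3L up 7.79-fold, the kinase ULK1 4.68-fold and GABARAPL1 2.49-fold. The list's camera adjusted p was 0.0421, and adjusted p = 0.272 with an estimated correlation. It lost the call with the replicate block (adjusted p = 0.0634), without normoxia replicate 1 (0.0555) and with GC trends within the groups removed (0.0526), over a range of 0.0376 to 0.272 in the camera alternatives, and the exact direction test did not call it (two-sided, adjusted p = 0.131). With the GC trend of each library removed, camera still called the autophagy list. Cholesterol genes had 8 of 25 members listed, 8 higher and 0 lower, 8 adjusted over the list alone. INSIG1, which retains sterol-regulated proteins in the endoplasmic reticulum, rose 3.42-fold, STARD4 2.44-fold and the transcription factor SREBF2 2.42-fold (camera adjusted p = 0.0355, and adjusted p = 0.218 with an estimated correlation). That call also ended with GC trends within the groups removed (adjusted p = 0.0526, range over the camera alternatives 0.0347 to 0.218). Removing the GC trend of each library left it in place.

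DNA replication genes fell. Of 41 members 24 had an entry, with 0 higher and 24 lower, and 24 adjusted over the list alone. The replication factor MCM10 fell by 2.82 on the log2 scale, from 1559 ± 180 to 221 ± 21.8 normalized counts. The G1/S cyclins CCNE2 and CCNE1 fell by 2.13 and 1.76, and the transcription factor E2F1 by 1.79. The list's median was -1.33 (camera adjusted p = 1.17e-06, and adjusted p = 0.0697 with an estimated correlation). Homologous recombination and mismatch repair genes had 5 of 20 members listed, 0 higher and 5 lower, 5 adjusted over the list alone. RBBP8, EXO1, BLM and RAD54L fell by 1.31, 1.22, 1.11 and 1.05 (camera adjusted p = 0.0416, and adjusted p = 0.389 with an estimated correlation). These repair genes have a median GC content of 41.2%, and their call ended with GC trends removed within the groups (adjusted p = 0.0526) or from each library (0.549), over a range of 0.0347 to 0.549 in the camera alternatives. Of 34 mitosis genes, 0 had an entry.

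Ribosome biogenesis genes fell as well, with 19 of 30 members listed, 0 higher and 19 lower, 19 adjusted over the list alone. RRS1 fell by 2.94 on the log2 scale, the RNA polymerase I subunit POLR1B by 2.10, NOLC1 by 1.96 and the rRNA methyltransferase NOP2 by 2.03. NOP2 shares 83.8% of its transcript sequence with other genes. The median of the list was -1.57 (camera adjusted p = 8.25e-06, and adjusted p = 0.0697 with an estimated correlation). Of 40 cytosolic ribosomal protein genes 0 had an entry, and of 32 mitochondrial ribosome genes 3, MRPL3, MRPL19 and MRPL20, which fell by 1.21, 1.12 and 1.09.

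Most listed antioxidant genes driven by NRF2 fell, with 10 of 21 members listed, 1 higher and 9 lower, 10 adjusted over the list alone. The aldo-keto reductase AKR1B10 fell by 2.45 on the log2 scale, from 99323 ± 4607 to 18224 ± 581 normalized counts. The sulfiredoxin SRXN1 fell by 2.31, OSGIN1 by 1.99, and the cystine transporter SLC7A11 went from a mean of 10684 to 2671 normalized counts (SE 0.27 on the log2 scale). SRXN1 shares 84.9% of its transcript sequence with other genes. The higher member was the heme oxygenase HMOX1 (log2 fold change 1.35), named after its value was seen. Camera gave adjusted p = 0.0103, and adjusted p = 0.212 with an estimated correlation.

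Replication-dependent histone genes rose, with 7 of 14 members listed, 7 higher and 0 lower, 7 adjusted over the list alone. H4C8 rose 49.0-fold, from 137 ± 21.8 to 6731 ± 356 normalized counts, H2AC8 5.76-fold, H2BC5 4.63-fold and H1-2 3.99-fold. The median was a 3.99-fold rise (camera adjusted p = 0.0311, and adjusted p = 0.272 with an estimated correlation). Interferon response genes had 7 of 24 members listed, 7 higher and 0 lower, 7 adjusted over the list alone, led by the transcription factor IRF7 (5.57-fold), IRF9 (4.60-fold), IFIT2 (2.83-fold) and IFIT3 (2.73-fold). As a list they missed the threshold (camera adjusted p = 0.0659, and adjusted p = 0.272 with an estimated correlation), and passed without hypoxia replicate 2 (0.0441) and with the GC trend of each library removed (0.0376), over a range of 0.0376 to 0.272 in the camera alternatives. The exact direction test called them (two-sided, adjusted p = 0.0453). fry also did (adjusted p = 3.87e-05), but it tests against no change and not against other entries. These entries had been selected as changed, so that call is no separate support. IRF9 shares its whole transcript sequence with another annotated gene.

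**Figure D2:**
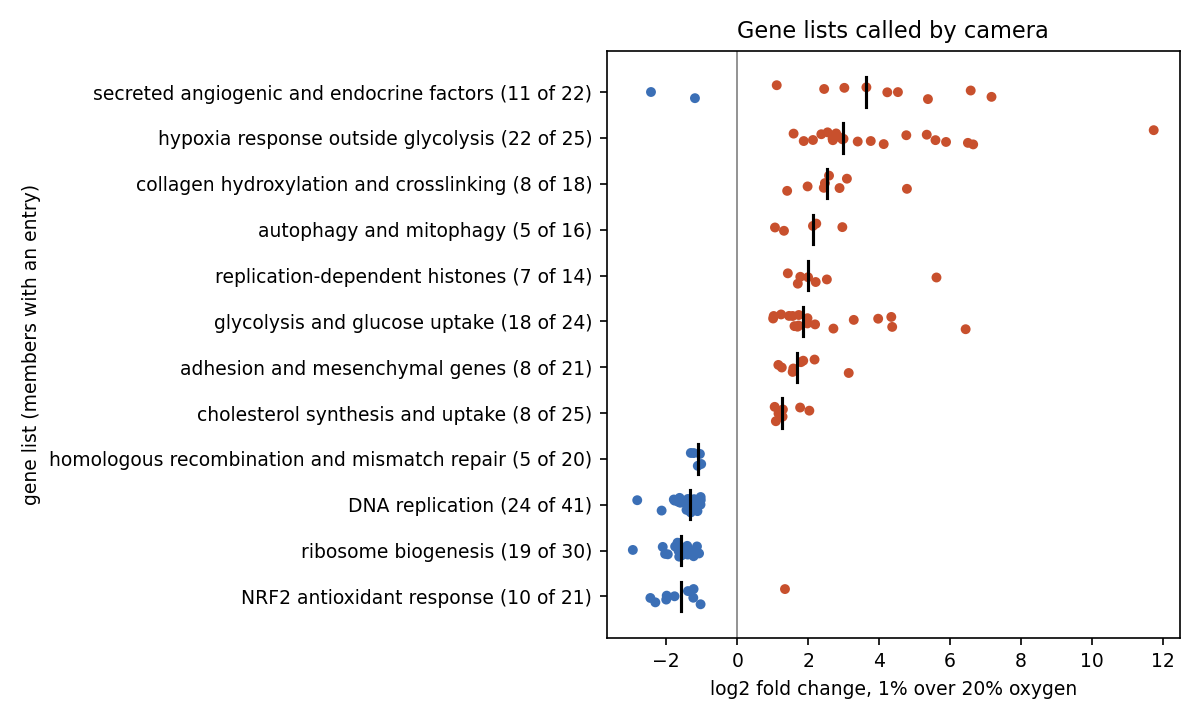
Log2 fold change (1% over 20% oxygen) of each listed member of the 12 gene lists that passed camera, one point per gene, red above 0 and blue below, with a black bar at the list median and the number of members with an entry in brackets. Medians run from -1.58 for NRF2 antioxidant genes to 3.64 for secreted factors, and no point lies between -1 and 1 because the table holds no such entries.

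Genes of hepatocyte identity went both ways. Of 30 plasma protein genes 7 had an entry, 3 higher and 4 lower, 7 adjusted over the list alone. AHSG and CP, which encode fetuin and ceruloplasmin, rose 5.16-fold and 4.09-fold, and APOB, the main apolipoprotein of very low density lipoprotein, fell by 2.10 on the log2 scale. The list's median was -1.28 (camera adjusted p = 0.654), while its fry test pointed up (adjusted p = 0.0476). Of 18 hepatocyte transcription factors 5 had an entry, 2 higher and 3 lower, 5 adjusted over the list alone. The pregnane X receptor NR1I2 rose 4.93-fold, and ONECUT2, CEBPA and FOXA1 fell by 2.54, 2.05 and 1.86 (camera adjusted p = 0.495). Of 30 metabolism enzymes 4 had an entry, 1 higher and 3 lower, 4 adjusted over the list alone: CYP3A5 rose 4.15-fold, and HPD, UGT1A1 and ALDH1A1 fell by 1.63, 1.28 and 1.24.

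Lipid genes also split. Of 14 fatty acid synthesis genes 7 were listed, 5 higher and 2 lower, 7 adjusted over the list alone, with ACSS2, ACACB and FADS2 up 3.54-fold, 2.94-fold and 2.89-fold and the elongase ELOVL6 down (fell by 1.89 on the log2 scale; camera adjusted p = 0.495). Lipid droplet and lipoprotein genes had 8 of 23 listed, 6 higher and 2 lower, 8 adjusted over the list alone, with HILPDA, PLIN2 and AGPAT2 up 7.97-fold, 3.36-fold and 2.86-fold (camera adjusted p = 0.358). Of 25 fatty acid oxidation genes 3 were listed, 1 higher and 2 lower, 3 adjusted over the list alone. The carnitine palmitoyltransferase CPT1A and the carrier SLC25A20 fell by 1.94 and 1.17, and ACADS rose 2.63-fold.

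Most mitochondrial energy genes had no entry. CYCS, cytochrome c, was the 1 entry among 57 nuclear respiratory chain genes and fell by 1.41 on the log2 scale, and 0 of 13 mitochondrially encoded genes were listed. Of 19 genes of the tricarboxylic acid cycle list 4 had an entry, 2 higher and 2 lower, 4 adjusted over the list alone. IDH3A and FH fell by 1.70 and 1.12, and IDH2 and the pyruvate carboxylase PC rose 2.63-fold and 2.58-fold. IDH3A shares 63.0% of its transcript sequence with ACSBG1 on the opposite strand.

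Stress lists were mixed. Integrated stress response genes had 10 of 24 listed, 7 higher and 3 lower, 10 adjusted over the list alone. DDIT4, an inhibitor of mTORC1, rose 27.2-fold and PPP1R15A 3.52-fold, and the serine enzyme PSAT1 fell by 1.75 (camera adjusted p = 0.510). Of 13 heat shock genes 4 were listed, 0 higher and 4 lower, 4 adjusted over the list alone: HSPH1, HSPA8, HSPD1 and DNAJA1 fell by 1.79, 1.36, 1.03 and 1.01. Of 23 endoplasmic reticulum chaperone genes 2 were listed, with the oxidase ERO1A up 5.84-fold and SDF2L1 down (fell by 1.26). NF-kB and acute phase genes had 5 of 20 listed, 4 higher and 1 lower, 5 adjusted over the list alone (camera adjusted p = 0.219). IL6 had 0 counts in each normoxia library and 48.4 ± 3.99 normalized counts in hypoxia, at least 48.4-fold higher, SOCS3 rose 4.49-fold and TNFAIP3 2.47-fold.

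The p53 target list had 5 of 16 members listed, 2 higher and 3 lower, 5 adjusted over the list alone, with ZMAT3 and TIGAR down (fell by 2.38 and 2.24) and BBC3 up 3.58-fold (camera adjusted p = 0.388). Iron and heme genes had 7 of 19 listed, 4 higher and 3 lower, 7 adjusted over the list alone, with the ferrireductase STEAP3 up from 1253 ± 56.8 to 10019.8 ± 403 normalized counts, TF up 3.17-fold and FECH down (fell by 1.81; camera adjusted p = 0.856). Among 20 jumonji and TET dioxygenases 5 were listed, 3 higher and 2 lower, 5 adjusted over the list alone. The demethylase genes KDM3A, KDM5B and KDM4B rose 3.89-fold, 3.39-fold and 2.90-fold, and RIOX1 fell by 2.11 (camera adjusted p = 0.941).

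Among markers of other cell types, 5 of 7 cholangiocyte markers were listed, 5 higher and 0 lower, 5 adjusted over the list alone, with TFF3 up 8.81-fold, KRT19 4.74-fold, KRT7 3.67-fold and AQP1 2.46-fold (camera adjusted p = 0.153). AQP1 lost its call under TMM (adjusted p = 0.0550, range over all alternatives 0.00482 to 0.418). Of 8 endothelial markers EGFL7 and CDH5 were listed and rose 9.26-fold and 7.15-fold. Of 9 leukocyte markers 1 was listed, the lysosomal protein gene CD68, up from 2303 ± 236 to 9209 ± 1291 normalized counts, which shares 98.5% of its transcript sequence with other genes. Of 9 fibroblast markers 0 had an entry.

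Some of the largest rises came from genes with no count in any normoxia library. PTH1R reached 432 ± 215 normalized counts, ZP1 143 ± 27.8, MYL3 111 ± 56.1 and DUOX2 107 ± 43.5, at least 432-fold, 143-fold, 111-fold and 107-fold higher. The annotated spans of PTH1R and MYL3 on chromosome 3 overlap, so their counts may not be separate. The platelet integrin ITGA2B rose 183-fold from 2.21 ± 3.82 normalized counts, the keratin KRT17 175-fold from 0.65 ± 1.13 and TNS1 122-fold from 1.55 ± 1.44. Their baselines rest on few reads, so these folds are imprecise. Without normoxia replicate 1, ITGA2B had 0 normoxia counts and was at least 283-fold higher, and without normoxia replicate 3 its fold was 122. KRT17 had 2 normoxia counts, both in replicate 2 (ratio of mean normalized counts 202, 95% exact Poisson interval of those counts 55.8 to 1666), and was at least 87.9-fold higher without that library. For TNS1 the ratio of mean normalized counts was 228 without normoxia replicate 1 (interval of the 2 remaining counts, 63.0 to 1880), and the FPKM values gave another ratio than the counts.

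The largest fall was in an entry at 0 counts in each hypoxia library. AC008878.3, outside the rule for names and chosen after its values were seen, had 898 ± 346 normalized counts in normoxia, at least 898-fold above the floor (adjusted p = 3.73e-05). It shares 98.9% of its transcript sequence with other genes, mostly ARHGEF18, so its count is uncertain. An unannotated entry, NewGene_6324, also had 0 counts in hypoxia and 91.6 ± 2.11 normalized counts in normoxia. Among genes named by the rule, the largest falls included the alcohol dehydrogenases ADH1C, which fell by 4.87 on the log2 scale, from 539 ± 68.8 to 18.3 ± 12.6 normalized counts, and ADH6 (fell by 4.40). The protease homologue PRSS35 fell by 4.62, the transcriptional coactivator PPARGC1B by 4.51, the osteoprotegerin gene TNFRSF11B by 3.83 and the transcription factor FOXQ1 by 3.77. KBTBD8, SLC9A4 and ISM1 fell by 3.72, 3.50 and 3.48, to 8.38 ± 9.13, 11.6 ± 12.5 and 9.16 ± 5.90 normalized counts. Some of these falls rest on few hypoxia reads and are imprecise. Without hypoxia replicate 1, ADH1C fell by 5.52, KBTBD8 fell by 4.91 and SLC9A4 fell by 2.89. SLC9A4 fell by 4.64 without hypoxia replicate 2, and PRSS35 fell by 4.02 without hypoxia replicate 3. An entry for MATR3 fell by 4.15, but it shares 98.7% of its transcript sequence with other genes, mostly a second gene of that symbol.

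In total 2675 of 2675 entries passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 1518 higher and 1157 lower at 1% oxygen. The share of higher entries was 56.7%, and 46.3% with RLE size factors, 39.7% with listed totals alone (997 and 763 higher entries against 1157 lower). RLE size factors, and those of DESeq2, moved the median log2 fold change by -0.78 and listed totals by -0.96. Upper quartile, FPKM-based and TMM scaling moved it by between -0.22 and -0.53. Each of these shifts is smaller than the smallest change in the table, so they could not turn a direction. Adjusted as if all 58780 genes of GENCODE 29 had been tested, 2131 entries passed, and APOB, UGT1A1, CXCL8, EXO1, MRPL20, ACADS, AGPAT2, SDF2L1, IFIT2, SLC9A4 and AQP1 did not.

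Direction moved with GC content. Entries higher at 1% oxygen had a median transcript GC content of 54.9% and entries lower 47.6%. Over 10 equal bins of GC content, the share of higher entries ran from 33.9% in the next to lowest bin to 75.9% in the top bin. The libraries of a group also differed among themselves: the slope of log2 count on GC content, per 10 points, was -0.09, -0.32 and -0.48 in normoxia replicates 1 to 3 and 0.20, 0.55 and 0.15 in hypoxia replicates 1 to 3. With the GC trend of each library removed, 2333 of 2485 entries passed and 0 changed sign.

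**Figure D3:**
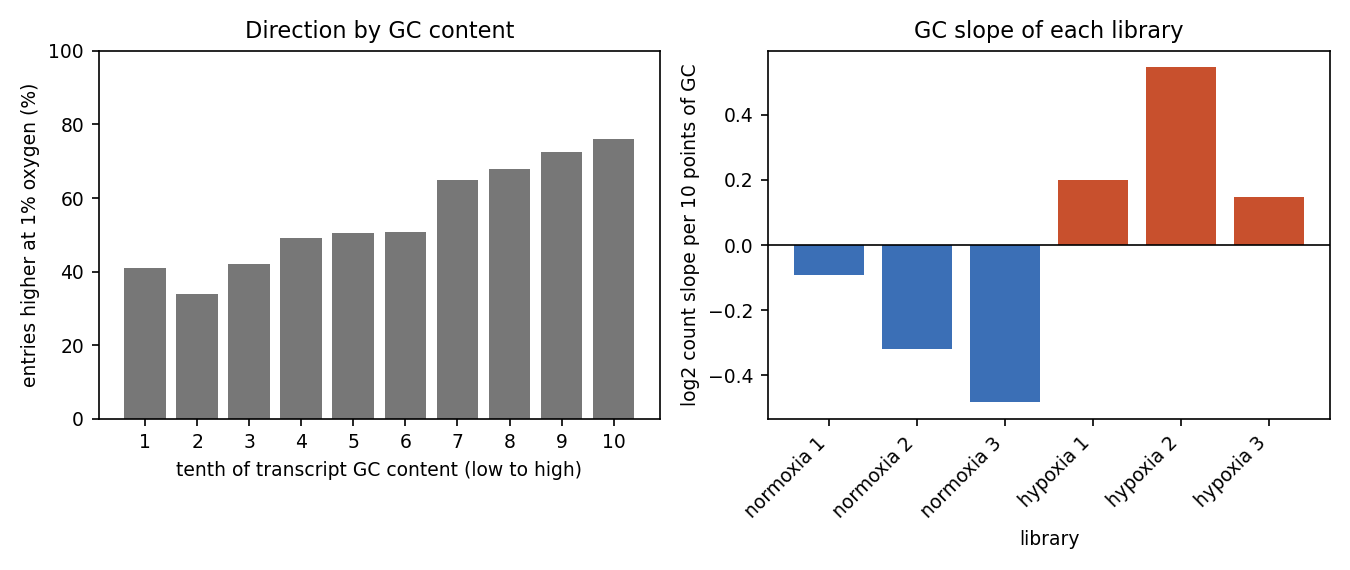
Left, the share of entries higher at 1% oxygen (bars, percent) in each of 10 equal bins of transcript GC content, from 33.9% in the next to lowest bin to 75.9% in the top bin. Right, the slope of log2 normalized count on GC content per 10 points in each library, against the mean of the 6 libraries, below 0 in the 3 normoxia libraries (blue) and above 0 in the 3 hypoxia libraries (red).

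**Figure D4:**
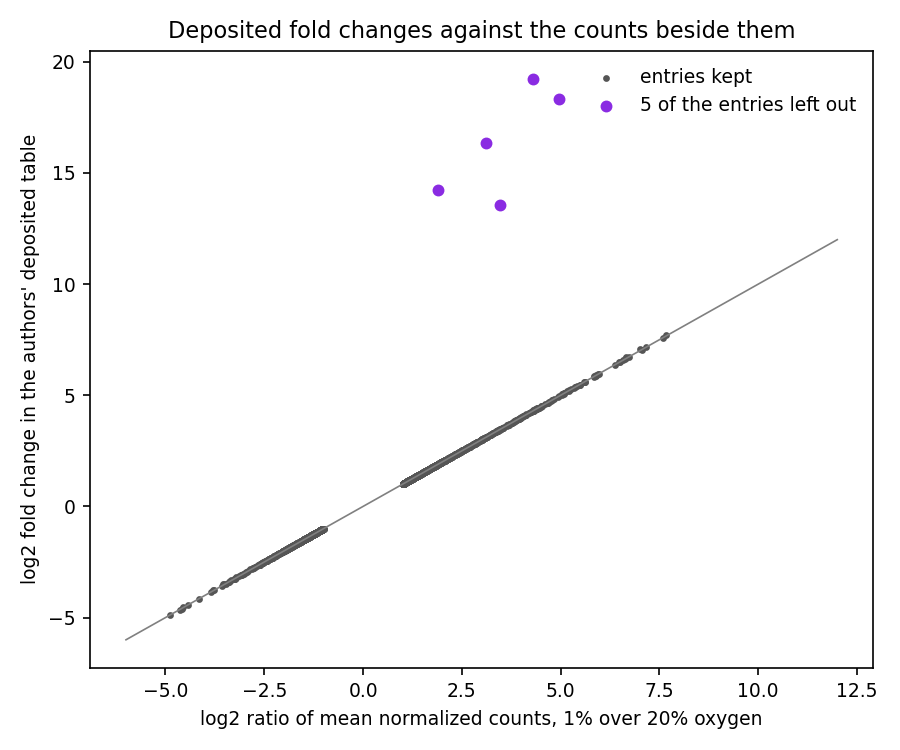
Log2 fold change in the authors' deposited table against the log2 ratio of mean normalized counts, one point per entry with counts in both groups, with the line of equality in grey. The 2663 entries kept lie on the line, deviating by a median of 0.000405, and 5 of the 6 entries left out are drawn (purple) and lie between 10.1 and 14.9 above it.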

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

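The tests on the 6 leading entries were all chosen after their values had been seen. These entries have the largest log2 fold changes in the authors' deposited table and lie outside the fits, because those values are far from what their own counts give. In the authors' deposited table the log2 fold changes include 19.24 for RP11-157L3.3, 18.32 for LINC01128, 16.34 for CTC-366B18.2, 14.23 for RP11-423O2.2 and 13.55 for MKLN1-AS. The normalized counts of these entries give 4.30, 4.95, 3.12, 1.90 and 3.48 in the same order. Those of the 6 found in GENCODE 29 are annotated as antisense or processed transcripts, and RP11-157L3.3 and RP11-423O2.2 were not found there, while 2484 of the 2675 other entries are protein coding and 190 are not in GENCODE 29.

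Low counts do not account for the gap: 789 other entries with all counts in the same range, 3 to 489, deviated from the authors' deposited table by a median of 0.00156 and at most 0.0264. A fold change taken from the FPKM values does not either, since the FPKM ratios of the 6 lie at least 11.61 below the log2 values in the authors' deposited table. A candidate explanation is that these entries were made by another procedure than the rest: all 6 have FPKM values with 7 or 8 decimals, against at most 6 decimals in the 2675 others (exact test, two-sided, p = 1.95e-18). In the authors' deposited table, 4 of the 6 have an FDR of 3 digits, against 0 of 2675, the FDR of RP11-423O2.2 shares its last 13 digits with that of DUOX2 and that of MKLN1-AS its last 13 with that of ANGPTL4, where the longest match between other entries with different values is 6. Higher expression at 1% oxygen stays open, as the hypoxia counts exceed the normoxia counts in 6 of 6 entries, but it cannot be told apart while the making of these values is unknown.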

How the results depend on the processing

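The recovered scale behind the main values was chosen after seeing the data, in place of the planned TMM, and so were the tests with FPKM-based scaling, adjustment over all GENCODE 29 genes, the 6 leading entries kept, GC trends removed and exact directions. The recovered scale is the authors' own, so the count of 2675 calls (1518 higher, 1157 lower) mostly repeats their selection. Calls of higher entries fell to 997 with RLE size factors and 763 with listed totals, scalings that assume little change over the listed entries as a whole, while 1157 lower entries passed in each. glmTreat, which tests for a change beyond 1 on the log2 scale, called 1668 entries, 635 of them lower. It ended the call of 18 named genes: ALB (adjusted p = 0.0502), FH, MRPL3, MRPL19, MRPL20, EXO1, BLM, RAD54L, STARD4, ACADS, SLC25A20, UGT1A1, SDF2L1, HSPD1, DNAJA1, IFIT2, GDF15 and AQP1. Across the 6 fits that left out 1 library, 2666 to 2675 entries passed, 1509 to 1518 higher and 1154 to 1157 lower, and 11 to 13 lists.

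Of the 23 lists, 12 passed camera, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 0 with an estimated correlation and GC trends within groups removed (6 at an unadjusted p under 0.05). fry, which does not compare a list with other genes, called 22. It tests against no change, and every entry had been selected as changed, so these calls are no separate support. It turned the hepatocyte plasma proteins from down to up (adjusted p = 0.0476), and the cause was not tested. With GC trends within groups removed and the preset correlation 8 lists passed (14 at an unadjusted p under 0.05). With the GC trend of each library removed 12 passed, where homologous recombination and mismatch repair lost its call and interferon response gained a call. Over named genes, 50 results under alternatives lost the call and 0 reversed, but scalings that shift all entries alike by under 1 could reverse none, and the low-count filters removed 0 entries. For lists, 256 held, 31 lost the call, 11 gained it and 1 reversed. With RLE, the named genes STARD4, ACADS, IFIT2, IFIT3, TNFAIP3 and AQP1 lost the call, and with listed totals also AGPAT2, GABARAPL1 and SNAI2. MRPL19 lost it with the GC trend of each library removed (adjusted p = 0.0514, range over all alternatives 1.96e-27 to 0.106). Its log2 fold change moved from -1.12 to -0.37 in that fit.

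The labels give both groups replicate numbers 1 to 3. Deviations from the group means correlated across entries at -0.38, -0.14 and 0.47 for equal numbers, and not every sample correlated best with its own number (normoxia 1 with hypoxia 2, 0.61), so the numbers were not taken to pair the samples. The deviations of normoxia 1 and hypoxia 2 rose with GC content (Spearman 0.568 and 0.599), and those of the other libraries fell. Such trends can produce these correlations, so the check can neither show nor exclude shared cultures. With the replicate block 2675 entries and 11 lists passed, and autophagy and mitophagy was the list that lost its call.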

Other observations

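Tests chosen after the result was seen are all those on pathways, the histone tests on direction, S phase and the HIST2H2AA3 and HIST2H2AA4 pair, the exact direction tests of lists, the removal of GC trends, and the comparison of DNA replication with mitosis. Pathways came from the KEGG column of the authors' deposited table, which covers 1254 entries (716 higher, 538 lower). Of 196 pathways with at least 10 entries, 24 had a direction that differed from the other entries (exact test, two-sided, Benjamini-Hochberg adjusted). That test takes entries as independent. Within bins of GC content 17 of the 24 stayed called, with camera at the preset correlation 10, and with an estimated correlation 0 of 196 were called (15 at an unadjusted p under 0.05). The genes named from them were chosen after their values were seen. Focal adhesion had 39 entries higher and 4 lower (adjusted p = 0.000134), with the integrin ITGB4 up by 3.37 on the log2 scale (SE 0.20), the laminin chain LAMB3 by 3.07 (SE 0.16) and the growth factor gene PDGFA up 13.9-fold. Extracellular matrix receptor interaction had 26 higher and 2 lower (adjusted p = 0.00200), and actin cytoskeleton regulation 31 higher and 4 lower (adjusted p = 0.00239). These pathways share members, among them ITGA2B, ITGB4 and ITGA5, and are not separate evidence.

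RNA polymerase subunits had 0 higher and 11 lower (adjusted p = 0.00239): the RNA polymerase III subunit POLR3K fell by 2.16 on the log2 scale. RNA transport had 2 higher and 29 lower (adjusted p = 2.31e-07), cell cycle 5 higher and 24 lower (adjusted p = 0.000583), led by the phosphatase CDC25A, which fell by 2.79, and the spliceosome 3 higher and 13 lower (adjusted p = 0.0328, and 0.0552 within bins of GC content). RNA transport and the KEGG pathway of ribosome biogenesis share members, among them RPP40, RPP25 and POP1. POLR1B is in the RNA polymerase pathway and in the fixed ribosome biogenesis list, so these falls are not separate evidence. Near the fixed lists, the exact test called ribosome biogenesis (adjusted p = 2.77e-09), DNA replication (0.0032), mitophagy (0.0122, and 0.211 within bins of GC content) and HIF-1 signaling (0.0352). It did not call glycolysis and gluconeogenesis (14 higher, 5 lower, 0.437), autophagy (21 and 6, 0.136) or cholesterol metabolism (9 and 1, 0.201), although the fixed lists of similar name passed camera. The leading entries of the mitophagy pathway include the unannotated NewGene_1972, NewGene_11712 and NewGene_4807, for which no GC content was found. Its value within bins of GC content is therefore not a test of GC content alone.

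Entries rich in GC were more often higher at 1% oxygen. Of 11 lists called by an exact direction test, 10 stayed called within bins of GC content, homologous recombination being lost (adjusted p = 0.16). This argues against GC content as the whole cause of the list directions only as far as entries are independent, which that test assumes. With GC trends within groups removed, camera called 8 lists at the preset correlation and 0 with an estimated correlation. Removing GC trends within groups lowered the common dispersion from 0.0492 to 0.0315. A GC bias that varies from library to library may account for part of the gradient: the group mean slopes differ by 0.595 per 10 GC points against a widest range of 0.397 within a group, a ratio of 1.5. With 3 libraries per group, such a bias and an effect of oxygen on GC-rich transcripts cannot be told apart from that ratio.

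All 12 replication-dependent histone entries were higher, against 1506 of 2663 others (exact test, two-sided, p = 0.00180). More cells in S phase would raise DNA replication genes too, and their median was -1.33. Reads shared between near-identical copies are argued against for most, with a median of 1.31% of 31-mers held by another histone gene, but may link the counts of HIST2H2AA3 and HIST2H2AA4 (at least 97.2% shared). Polyadenylated histone transcripts are a candidate explanation, as a hypothesis only. A spliced or over 1000 nt transcript is annotated for 8 of 12 histone genes with an entry and 17 of 59 without (exact test, two-sided, p = 0.0195). That test bears on which histone genes have an entry, and those without can be unchanged or not counted. It cannot say why the entries were higher at 1% oxygen. Differentiation, oxygen or RNA handling as a source of polyadenylated histone transcripts was not tested.

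Neighbouring entries within 100 kb shared a direction in 565 of 799 pairs (70.7%), against 50.5% with directions shuffled (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The share was 70.1% in 314 pairs on opposite strands that do not overlap (one-sided permutation p = 1e-05), and with shuffling within bins of GC content 54.1% was expected over all pairs (one-sided permutation p = 1e-05). Of 41 DNA replication genes 24 had an entry and of 34 mitosis genes 0 (exact test, two-sided, p = 6.34e-09). That test takes genes as independent, although genes of a list can move together. A gene without an entry can still have changed, so 0 of 34 is not a measured lack of change. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2675 calls, 1 of 10 with as many, and the highest of the others 0. The entries had been selected as changed for that very split, so this contrast follows from the selection and is no evidence of an oxygen effect.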
